A study of Mus musculus with 2 samples.

How the data were processed

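The data were H3K9me3 ChIP-seq peak lists from the heart of B6NCrl mouse embryos at embryonic day 11.5, in 2 biological replicates of pooled male and female embryos. Per the labels, replicate 1 was 1 library from 109 embryos and replicate 2 combined 2 technical replicates. The number of embryos in replicate 2 was not given in the sources used here. The labels call these biological replicates, and every statement on spread rests on n = 2.

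The authors deposited 4 peak lists in narrowPeak format on mm10, per the text deposited with the replicates. There was 1 list for each replicate, 1 called on the alignments of both together, and 1 named replicated that was derived from the other 3. The signal value of each peak is a score that the authors deposited, and its definition was not given, although the narrowPeak format reserves the column for overall enrichment. It was used to describe, rank and filter peaks, and in the tests of explanations at the end. Values of 2 lists are set side by side as deposited. The p and q of each peak were deposited as −log10 values, as is usual for the narrowPeak format, and the lowest −log10 p in any list was 2.0. The aligner, the peak caller, their versions, the mapping filter and the rule for keeping a peak as replicated were not given in the sources used here. The control libraries and the reads were not analysed here. All 20035 replicated peaks had the same coordinates and values in the list called on both replicates. All 13767 peaks of that list that overlapped a peak of each replicate by at least 50% of either peak were kept as replicated, and so were 6268 others.

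Depth could not be read from the lists, so it is unknown, and no statement on undetected marks was made below the peak threshold. A gene without a peak is one where no peak was called, not one shown to lack the mark.

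Peak coordinates were set beside the GRCm38 sequence, which is the same assembly as mm10, and GENCODE release M21. No peak ended past its chromosome, and 0 peaks lay wholly in runs of N. The replicated peaks on the 21 main chromosomes (19 autosomes, X and Y), with 2647.52 Mb of known sequence, entered the tests, and peaks on contigs outside them were left out of the tests and are described at the end. Coordinates are given from 1, as a genome browser shows them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

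Peaks were called shared when they overlapped by at least 1 bp. A gene was called marked when at least 1 replicated peak overlapped its body. Peak midpoints were assigned in this order to promoters (within 1 kb of the start of a protein-coding transcript), exons and introns of protein-coding genes, and intergenic sequence. Intergenic thus means outside protein-coding genes and their promoters, and can include genes of other types. Each observed share was set against 1000 rotations of the peaks along each chromosome, in coordinates without runs of N (seed 11), which kept the widths and spacing of the peaks and the clustering of the genes. The two-sided permutation p counts rotations at least as extreme on either side, and the smallest it can give is 0.002. It was adjusted by the Benjamini-Hochberg method over 16 gene lists or 4 context classes, with a threshold of 0.05. The rotation tests ask whether the peaks of this list lie where they do by chance along the genome, and say nothing of differences between embryos.

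The 16 gene lists, the tests and the rule for naming genes were set before the data were examined. Named were up to 4 members of each list with the highest signal value of a replicated peak that overlapped peaks in both replicates, the 10 protein-coding genes outside the lists with the highest such value, the 5 protein-coding genes with the most covered sequence and the 5 strongest peaks. Means and SDs of signal values are over the strongest overlapping peak of each replicate. After the data were seen, symbols of major histocompatibility genes were taken out of the histone list and an autosomal Mage gene out of the X-linked list; the lists as first written were run as an alternative. The share of peaks in coding sequence and the positions in 10 equal parts of the gene body were also chosen after the data were seen.

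The list test was tested on simulated data. Of 640 lists tested on randomly rotated peak lists, 19 (2.97%) had a p below 0.05. The rotated peak lists were made in the same way as the background of the test, so a low rate follows by construction. That rate cannot show how often the test would call a list because peak density differs between regions of the genome. Marks were planted in 40% of germline genes, 40% of Hox genes, 30% of cytochrome P450 genes or 20% of vomeronasal genes. They were recovered, with a p below 0.05, in 10 of 10 simulations each. These marks were added to those that the rotated lists already held, so a planted share is not the whole simulated share. The whole shares observed in the data were 23.9% for germline, 0% for Hox, 23.8% for cytochrome P450 and 22.3% for vomeronasal genes. Recovery therefore does not show that the test would find marks of the observed size in lists that did not pass. Shares below rotation were not simulated.

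Alternatives were an overlap of 50% in 1 or both directions, a −log10 p of at least 5, a signal value of at least 5, the 5000 strongest peaks, the stronger part of the replicated list above its median signal value, the list of each replicate alone, promoters within 2 kb, peaks near transcript starts only, peaks with 50% of their length in the gene, peak summits in place of midpoints, and 10000 random lists of genes matched on length. Replicated peaks that overlap a peak of each replicate were added as an alternative after the data were seen.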

Results

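The mark measured was trimethylation of lysine 9 of histone H3 (H3K9me3), a modification of heterochromatin and silenced genes, in the heart of mouse embryos at embryonic day 11.5. Heart tissue of both sexes was pooled from B6NCrl embryos, and chromatin bound by an antibody against the mark was sequenced (ChIP-seq) in 2 biological replicates of this single group. Replicate 1 came from 109 pooled embryos and 1 technical replicate, and replicate 2 combined 2 technical replicates. With 1 tissue, 1 age and no second condition, the data allowed a comparison of the replicates and a description of where the mark lay, not a comparison between conditions.

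Replicate 1 held 49189 peaks that covered 13.1 Mb, and replicate 2 held 51177 peaks that covered 15.2 Mb (mean 50183 ± 1406 peaks, SD, n = 2). A list called on both replicates together held 28226 peaks, and the authors' replicated list kept 20035 of these. Replicated peaks were short, with a median width of 300 bp and a longest peak of 10946 bp, and covered 7.44 Mb. The authors' signal value, a score per peak, had a median of 3.08 in replicate 1, 3.19 in replicate 2 and 3.20 in the replicated list. Many peaks were weak: a q of at most 0.05 was reached by 28.6% of the peaks of replicate 1, 69.5% of those of replicate 2 and 45.6% of the replicated list. Read depth is unknown, since the peak lists hold no read counts.

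The first comparison asked how far the replicates marked the same places. Of the replicate 1 peaks on the 21 main chromosomes, 15865 of 48869 (32.5%) overlapped a replicate 2 peak, and of the replicate 2 peaks 15481 of 50886 (30.4%) overlapped a replicate 1 peak. Strong peaks overlapped a peak of any strength in the other replicate more often than weak ones did: in the 10% with the highest signal value, 64.7% were shared in replicate 1 and 62.2% in replicate 2, and in the 10% with the lowest 25.3% and 21.6%. When both lists were limited in the same way, the shared percents of replicates 1 and 2 were 25.3% and 23.8% for the 5000 strongest peaks of each, 38.6% and 18.5% for a signal value of at least 5, and 36.0% and 20.8% for a −log10 p of at least 5. They were 18.7% and 17.9% for a reciprocal overlap of at least 50%, and each of these exceeded rotation (two-sided permutation p = 0.002). Peaks on chromosome 7 were shared most often among the autosomes, at 45.2% in replicate 1 and 40.4% in replicate 2, and X peaks least often among all chromosomes, at 14.2% and 18.9%. When one list was rotated along each chromosome, a mean of 1.21% of the replicate 1 peaks and 1.17% of the replicate 2 peaks overlapped, so the observed sharing was 26.7-fold and 26.0-fold higher (two-sided permutation p = 0.002 for both, the smallest that 1000 rotations can give). Across the 16138 replicate 1 peaks with an overlapping partner, on contigs and chromosomes, the signal values of the replicates had a Spearman rho of 0.229 and a Pearson r of 0.295 on the log2 scale. These are correlations across peaks, which are not independent replicates.

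Of the 28226 peaks called on both replicates together, the authors kept 71% as replicated (Wilson 95% interval 70.4 to 71.5, which covers counting error only). The share was 96.0% among peaks with a −log10 p of at least 5. A peak of both replicates lay under 14135 replicated peaks (70.6% of the list), a peak of replicate 2 only under 4400, a peak of replicate 1 only under 1447, and no peak of either replicate under 53. Thus 29.4% of the replicated list did not overlap peaks of both deposited single-replicate lists, and the strongest peak given for each gene was taken from those that did.

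The highest signal values in the replicated list belonged to intergenic sequence, to zinc finger genes and to a testis gene. The strongest peak, at chromosome 16 positions 3231547 to 3232892 (mm10), had a signal value of 11.8, with 10.8 in replicate 1 and 12.4 in replicate 2 (mean 11.6 ± 1.18, SD, n = 2). It was intergenic, 358822 bp from the nearest protein-coding gene, the olfactory receptor gene Olfr161, and another of the 5 strongest peaks lay beside it, at 3233598 to 3234828 (8.95 ± 0.548, SD, n = 2). An intronic peak of Zfp981 at chromosome 4, 146535897 to 146536604, had 9.44 ± 1.16 (SD, n = 2). A peak in the coding sequence of Zfp810 at chromosome 9, 22278113 to 22279339, had 8.48 ± 1.07 (SD, n = 2). The peak at the promoter of Tcfl5, a transcription factor gene of the testis, at chromosome 2, 180642670 to 180644195, had 8.43 ± 1.90 (SD, n = 2).

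Imprinted genes, which are expressed from 1 parental allele, were marked far more often than rotated peaks would mark them. At least 1 replicated peak overlapped 32 of 40 (80%), against a mean of 22.2% after rotation. Some of these genes overlap each other, such as Kcnq1 and Kcnq1ot1 or Gnas and Nespas, so 1 peak can count for several. The marked genes held 81 distinct peaks. Impact, a translational regulator gene, carried an intronic peak on chromosome 18 at 12971896 to 12974169 with a signal value of 6.78 in replicate 1 and 5.14 in replicate 2 (mean 5.96 ± 1.16, SD, n = 2). The peak at chromosome 6, 58906487 to 58907873, lay over Nap1l5, a gene within an intron of Herc3, and so counted for both (5.34 ± 0.288, SD, n = 2). Inpp5f, a phosphoinositide phosphatase gene, had a peak at an internal promoter on chromosome 7, at 128688240 to 128688684 (5.0 ± 1.60, SD, n = 2). Counting only peaks within 1 kb of a transcript start, 24 of 40 imprinted genes (60%) were marked, against 4.47% after rotation. The adjusted permutation p was 0.00799 for the gene bodies and 0.0107 for the transcript starts (two-sided, Benjamini-Hochberg over 16 lists).

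The clustered protocadherin genes, which encode neuronal cell adhesion molecules, had the highest marked share of the 16 lists. Peaks overlapped 52 of 57 (91.2%), against 28.7% after rotation (adjusted permutation p = 0.00799), and 44 of 57 (77.2%) had a peak within 1 kb of a transcript start, against 1.56% after rotation (adjusted permutation p = 0.0107). The cluster, at chromosome 18 from 36930184 to 37841873, held 243 replicated peaks. Pcdhga1 overlapped 74 peaks, Pcdhga2 70, Pcdhga3 67 and Pcdhgb1 60, and the bodies of these genes overlap, so that a peak can count for many of them. The strongest peak in all 4, at 37752677 to 37754726, lay in an intron of each and in coding sequence of Pcdhgb7, and had a signal value of 6.20 in replicate 1 and 7.24 in replicate 2 (mean 6.72 ± 0.735, SD, n = 2). The protein-coding genes with the most covered sequence were the read-through models Gm42416 (106883 bp), Gm37013 (104352 bp) and Gm37388 (103301 bp), which span most of the cluster, followed by Pcdhga1 (45342 bp) and Pcdhga2 (43616 bp).

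**Figure D1:**
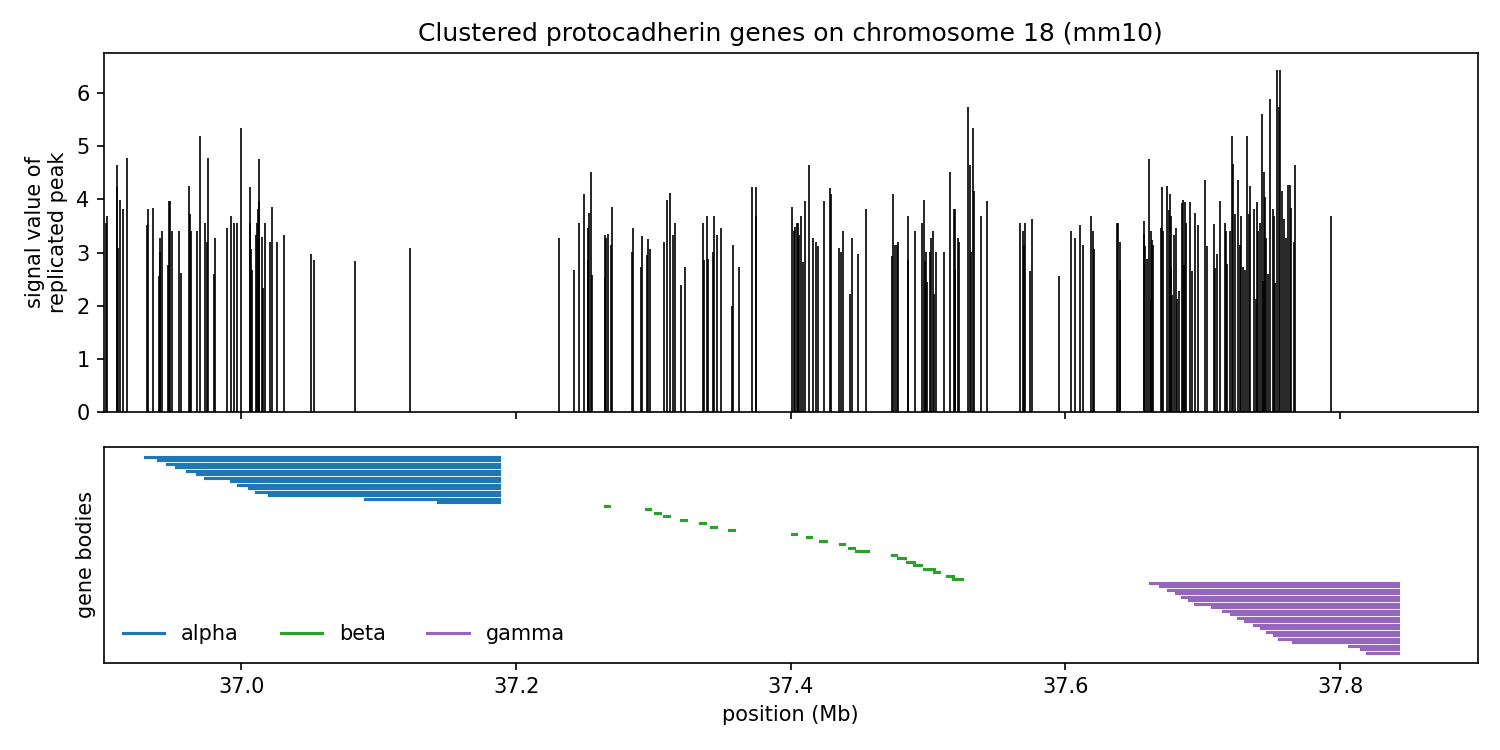
Replicated peaks in the protocadherin cluster on chromosome 18 (mm10). The upper panel gives each replicated peak as a line at its position in Mb, with the authors' signal value as its height, and the lower panel gives the bodies of the 57 listed genes, coloured by subcluster; peaks lie over all 3 subclusters, and the highest, at 6.43, lies in the gamma subcluster.

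Zinc finger genes, many of which encode transcription factors that silence transposable elements, were marked in 145 of 391 cases (37.1%), against 14.7% after rotation (adjusted permutation p = 0.00799). Zfp981 overlapped 15 replicated peaks, Zfp68 11, Zfp810 10 and Zfp2 9. The strongest peak of Zfp2 lay in its coding sequence at chromosome 11, 50899763 to 50901731, with 8.07 ± 0.594 (SD, n = 2), and that of Zfp68 lay in an intron at chromosome 5, 138608051 to 138608361, with 7.59 ± 1.25 (SD, n = 2). Of 519 peak midpoints inside zinc finger genes, 385 (74.2%) lay past the midpoint of the gene on its 3′ side, against 49.8% after rotation (two-sided permutation p = 0.004). Coding sequence held 150 of the 519 (28.9%), against 7.01% after rotation (two-sided permutation p = 0.002, unadjusted). The same share did not pass for protocadherins (62.7%, against 20.9%, permutation p = 0.172) or imprinted genes (11.4%, against 3.47%, permutation p = 0.152). Nor did it for vomeronasal genes (5.94%, against 10.1%, permutation p = 0.298). The last 10% of the length of zinc finger genes held 20.6% of their 519 midpoints and the first 10% of it 0.963%, while in other protein-coding genes the corresponding shares were 9.38% and 12%. Within 1 kb of a transcript start, 27 of 391 zinc finger genes (6.91%) had a peak, against 3.19% after rotation, which did not pass the test (adjusted permutation p = 0.120). That share was still 2.17 times rotation, near the 2.52 times of the gene bodies.

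**Figure D2:**
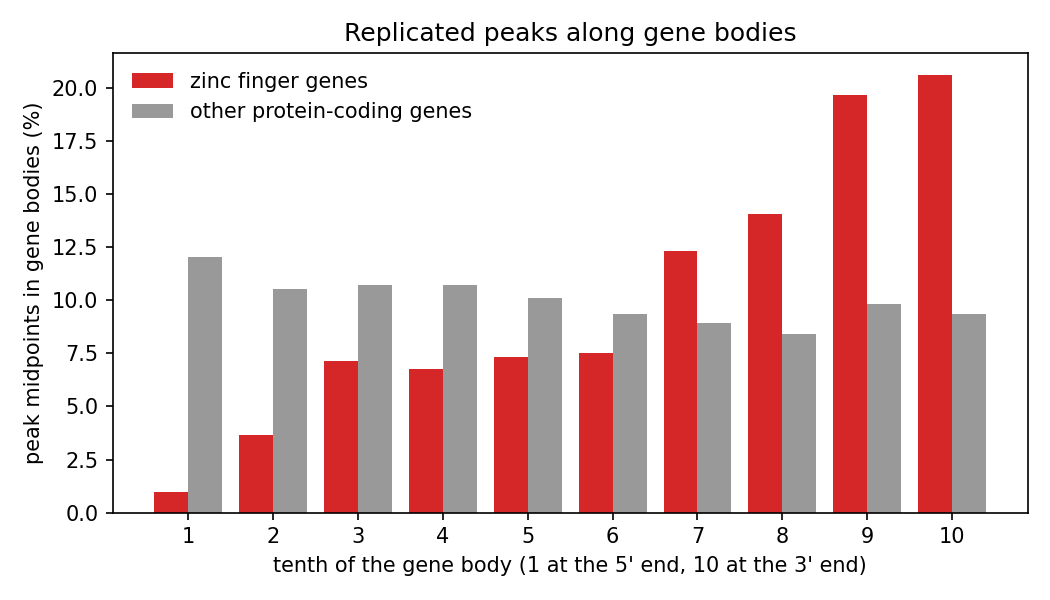
Position of replicated peaks along gene bodies. The horizontal axis divides each gene body into 10 equal parts from the 5′ end to the 3′ end, and the bars give the percent of peak midpoints in each part for 519 midpoints in zinc finger genes and 7701 in other protein-coding genes, a midpoint counting once for each gene it lies in; the zinc finger bars rise to 20.6% in the last part, and the others stay between 8.41% and 12%.

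Vomeronasal receptor genes, which encode pheromone receptors, were marked in 73 of 327 cases (22.3%), against 11.1% after rotation (adjusted permutation p = 0.00799). Vmn2r53 overlapped 8 replicated peaks, Vmn1r181 4, Vmn1r65 3 and Vmn2r70 1, all on chromosome 7. Their strongest peaks had signal values of 5.44 ± 1.46 for Vmn2r53, 5.87 ± 1.38 for Vmn1r181, 4.72 ± 0.583 for Vmn1r65 and 4.76 ± 0.193 for Vmn2r70 (SD, n = 2 each). The call did not hold with the replicate 2 peaks alone (30.3%, against 22.1% after rotation, adjusted permutation p = 0.0799). It was also lost with the replicated peaks that overlap a peak of each replicate (55 of 327, 16.8% against 8.74%, adjusted permutation p = 0.0719), although the share was 1.92 times that after rotation, near the 2.01 times of the whole replicated list.

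Germline genes did not pass the test over their whole bodies, where 11 of 46 were marked (23.9%, against 15.5% after rotation, adjusted permutation p = 0.362). Their transcript starts did: 6 of 46 (13%) had a peak within 1 kb, against 2.08% after rotation (adjusted permutation p = 0.0107). The promoter peak of Ddx4, an RNA helicase gene of germ cells, at chromosome 13, 112651743 to 112652513, had 5.40 ± 0.665 (SD, n = 2). Promoter peaks also lay at Taf7l on the X chromosome, 134475339 to 134476410 (4.51 ± 0.152, SD, n = 2), and at Dazl on chromosome 17, 50293263 to 50294173 (4.20 ± 0.284, SD, n = 2). Sycp1, a gene of the synaptonemal complex, had 1 on chromosome 3, at 102935797 to 102936270, over a UTR (3.99 ± 0.451, SD, n = 2). The replicates differed over the gene bodies of this list: replicate 2 alone marked 27 of 46 (58.7%, against 33.3% after rotation, adjusted permutation p = 0.00799) and replicate 1 alone 16 of 46 (34.8%, against 35.0%, adjusted permutation p = 1). The difference between the replicates was not itself tested.

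Genes of the heart and of other lineages were marked no more often than rotation gave. Of 40 cardiomyocyte genes 6 were marked (15%, against 20.8% after rotation, adjusted permutation p = 0.564), and none had a peak within 1 kb of a transcript start. The marked members with the highest signal values were ion channel, gap junction and sarcomere genes with intronic peaks: Cacna1c (5.40 ± 2.26), Scn5a (3.35 ± 0.0046), Gja5 (3.30 ± 0.305) and Tpm1 (3.29 ± 0.897; SD, n = 2 each). In Cacna1c, a calcium channel gene, the replicates gave 3.80 and 7.0. With the replicate 2 peaks alone, the share of cardiomyocyte genes lay below rotation (7 of 40, 17.5% against 36.8%, adjusted permutation p = 0.0128), while replicate 1 alone gave no call (12 of 40, 30% against 37.5%, adjusted permutation p = 0.543). Of 29 genes of other heart cell types 4 were marked (13.8%, against 17.7%, adjusted permutation p = 0.895), among them the endothelial genes Tek (4.45 ± 0.629) and Pecam1 (3.84 ± 0.198) and the epicardial gene Aldh1a2 (2.65 ± 0.412; SD, n = 2 each), each with an intronic peak. Of 40 regulators of other lineages only Esrrb, a pluripotency factor gene, was marked, in an intron (3.56 ± 0.188, SD, n = 2; adjusted permutation p = 0.428 for the list).

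The remaining lists did not pass the test either. Cytochrome P450 genes, which encode oxidases of steroids and drugs, were marked in 19 of 80 cases (23.8%, against 14.7%, adjusted permutation p = 0.362), with 12 peaks over Cyp3a16 and 6 over Cyp3a11. Their strongest peaks had signal values of 4.17 ± 0.674 for Cyp3a16, 4.29 ± 0.846 for Cyp3a11, 4.17 ± 0.674 for Cyp2b13 and 3.47 ± 0.936 for Cyp3a25 (SD, n = 2 each). Olfactory receptor genes were marked in 75 of 1093 cases (6.86%, against 4.71%, adjusted permutation p = 0.362), with mean signal values from 4.14 to 4.38 (n = 2) in Olfr1347, Olfr342, Olfr1349 and Olfr345. Marked were also 3 of 65 X-linked multicopy genes (Rhox13, Magea2 and Mageb16; adjusted permutation p = 0.631), 1 of 95 histone genes (H2afy2, a macroH2A gene; adjusted permutation p = 1) and 1 of 64 defensins (Defb33; adjusted permutation p = 1). Rhox13, a homeobox gene, had the strongest of these peaks, at 4.81 ± 1.15 (SD, n = 2). No replicated peak overlapped any of 39 Hox genes, 82 ribosomal protein genes or 110 keratin and keratin-associated protein genes, and rotation gave 3.79%, 3.55% and 2.49% (adjusted permutation p = 0.797, 0.332 and 0.362). Over all 21938 protein-coding genes, 3036 were marked (13.8%), below the 15.4% after rotation (two-sided permutation p = 0.002). This did not hold at a −log10 p of at least 5 (5.89%, against 5.77%, permutation p = 0.609), among the peaks at or above the median signal value (8.94%, against 9.39%, permutation p = 0.0679) or within 1 kb of transcript starts (2.13%, against 2.43%, permutation p = 0.0599).

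**Figure D3:**
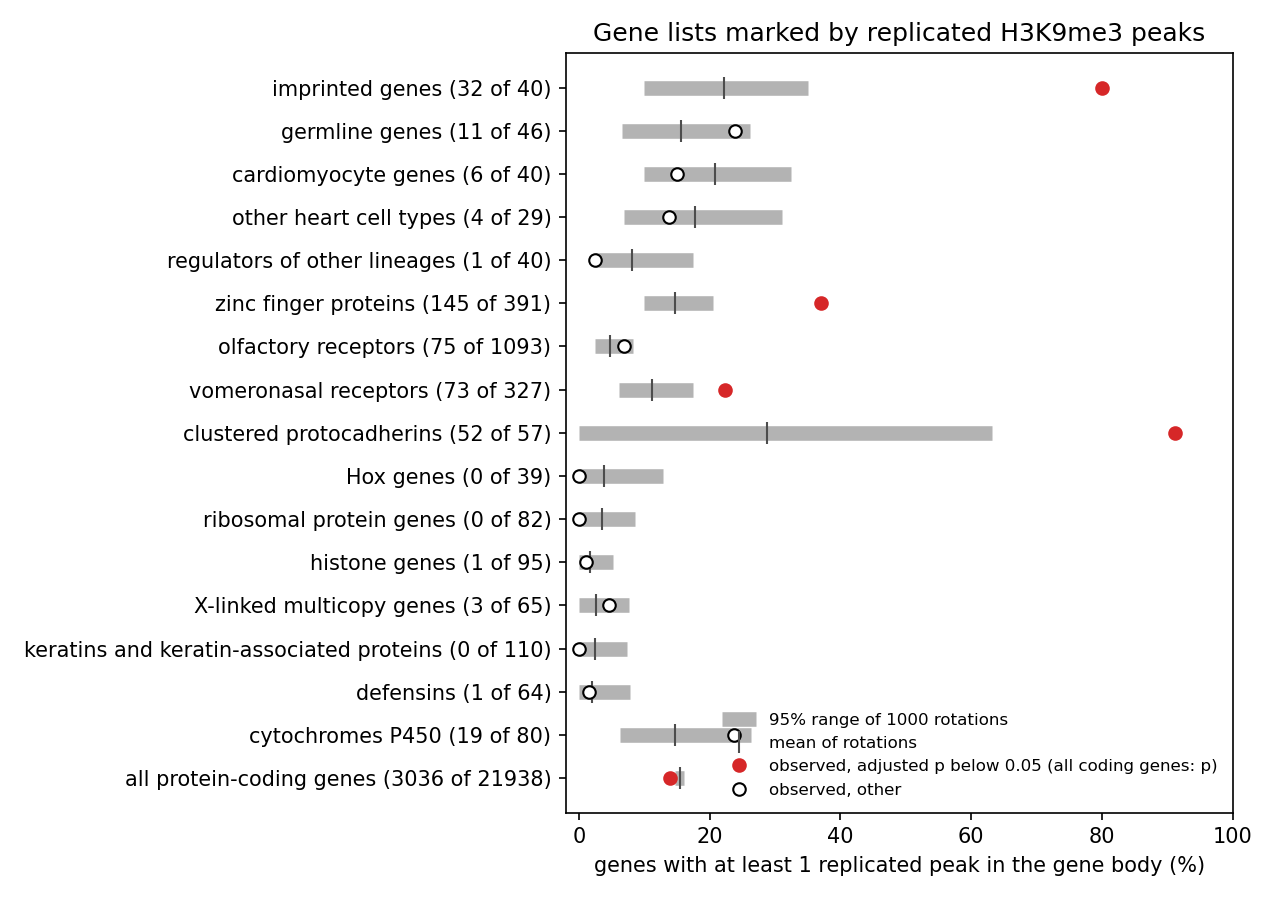
Percent of the genes of each list with at least 1 replicated peak in the gene body. Points are observed shares with the marked and total genes in the labels, grey bars the 95% range of 1000 rotations and ticks their mean; imprinted genes at 80%, clustered protocadherins at 91.2%, zinc finger proteins at 37.1% and vomeronasal receptors at 22.3% lie above their bars.

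Outside these lists, the genes with the highest signal values were of varied function. The lists are fixed sets, so a gene outside them may still belong to a listed class, such as the imprinted genes. Polrmt, the mitochondrial RNA polymerase gene, had a peak of 8.43 ± 0.165 (SD, n = 2) at chromosome 10, 79736728 to 79741685, over its coding sequence. Klf14, a transcription factor gene, had 8.32 ± 1.30 over a UTR. It lies on chromosome 6 at 30956023 to 30959078, near the listed imprinted gene Mest at 30723547 to 30748465. Tcfl5 had the promoter peak given above, and the gene model Gm49394 had 7.90 ± 2.0 at its promoter, within Igf2os, on chromosome 7, 142669195 to 142670727. Gm21887 (7.78 ± 0.610) and the melatonin synthesis gene Asmt (6.73 ± 2.70) lay on the X chromosome. In the replicated list the Gm21887 peak had a −log10 p of 73.8 at a signal value of 7.89, against 33.4 at 9.43 for the Zfp981 peak. The remaining genes named outside the lists were D130040H23Rik (7.42 ± 2.98), the glutamate transporter gene Slc17a7 (7.08 ± 2.08), Habp4 (6.84 ± 1.92) and the ciliary gene Nphp4 (6.55 ± 2.29), where SDs are over n = 2 replicates. In D130040H23Rik the replicates gave 5.31 and 9.52, so its rank depends on the replicate.

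By gene context, the mark lay mostly outside protein-coding genes and their promoters. Of 19794 replicated peaks on the main chromosomes, 13171 (66.5%) were intergenic, against 57.9% after rotation, and 5215 (26.3%) were in introns, against 36.0%. Exons held 858 (4.33%), against 3.35%, and these 3 classes passed the test (adjusted permutation p = 0.00266 each, two-sided, Benjamini-Hochberg over 4 classes). Promoters held 550 (2.78%), against 2.76%, with an adjusted permutation p of 0.931. The exon excess was not seen with the replicate 2 peaks alone (3.34%, against 3.29%, adjusted permutation p = 0.703), where the promoter share fell below rotation (2.26%, against 2.68%, adjusted permutation p = 0.00533).

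Replicated peaks held less repeat-masked sequence than rotated ones. The soft-masked share was 25.2% of their bases, against 34.0% after rotation (two-sided permutation p = 0.002) and 36.4% in the main chromosomes. The GC content was 47.0% in the peaks and 41.7% in the main chromosomes. Repeats to which reads could not be placed uniquely may be missing from any peak list, and the mapping filter was not given in the sources used here.

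Chromosome 7 was the most densely marked chromosome, with 2911 replicated peaks, or 20.5 per Mb of known sequence, 2.74 times the density over the 21 chromosomes. In the replicates' own lists the ratio was 2.14 ± 0.0679 (SD, n = 2). Chromosome 17 followed with 1.87 in the replicated list and 1.67 ± 0.0602 in the replicates, and chromosome 5 with 1.41 and 1.33 ± 0.0803 (SD, n = 2 each). The gap between chromosomes 7 and 17 was larger than the spread between the replicates. The X chromosome had 396 replicated peaks and a relative density of 0.324, and the replicates differed there, with 0.726 in replicate 1 and 0.511 in replicate 2 (0.618 ± 0.152, SD, n = 2). The Y chromosome had 10 replicated peaks.

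**Figure D4:**
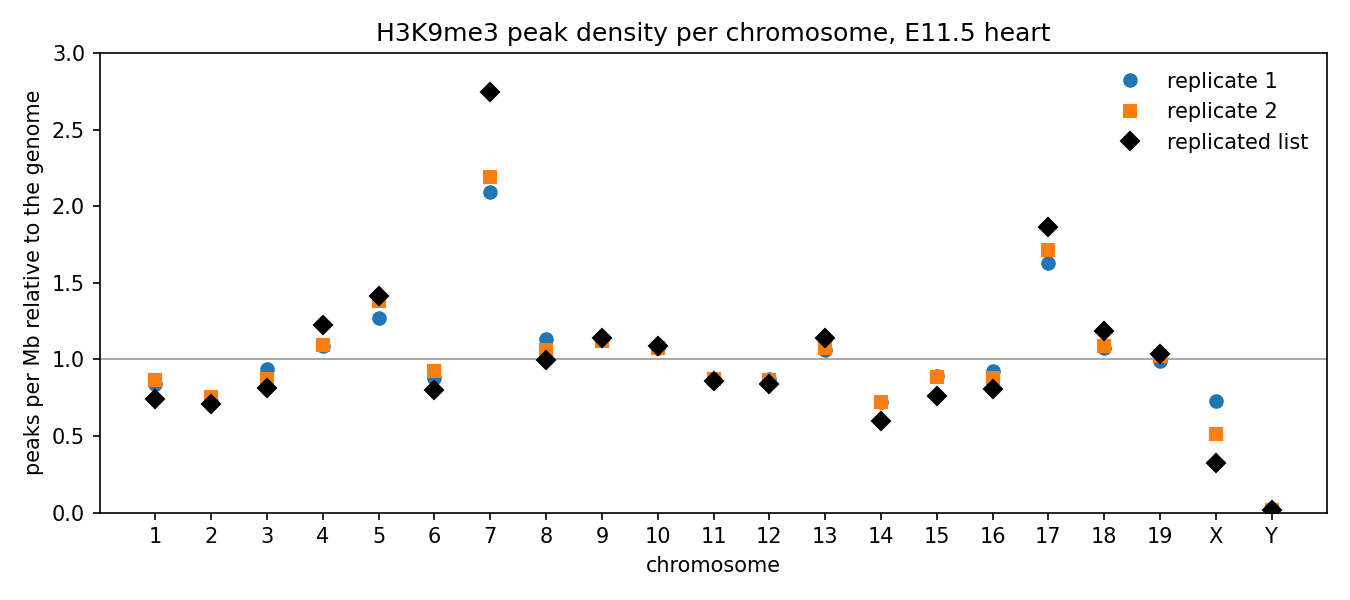
Peak density of each chromosome relative to the 21 main chromosomes together. The vertical axis gives peaks per Mb of known sequence divided by the value over all 21, with circles for replicate 1, squares for replicate 2, diamonds for the replicated list and a line at 1; chromosome 7 lies highest at 2.74 in the replicated list, and X lies at 0.324.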

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

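The tests of the calling threshold in replicate 1, of GC content and of both explanations for the contig peaks, the odds of X against Y peaks, the test of weaker X peaks in replicate 2, and the measures of spread for the gaps on chromosome 7 were chosen after the results were seen; the others were set down before the value they measure was known.

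Peaks appeared on sequence outside the main chromosomes, which the rotation tests left out. The replicated list held 241 peaks on 21 unplaced or unlocalized contigs. They covered 187 kb, and 11 of the 25 replicated peaks with the highest −log10 p lay on the contig JH584304. The 50 peaks of that contig had a median signal value of 2.92, against 3.20 on the main chromosomes, and a −log10 p of up to 76.6. Of the 25, 7 lay on chromosome 11 at 3184204 to 3200111, 5 on chromosome 13 at 119488009 to 119617730, 1 on chromosome 16 and 1 on X. The highest −log10 p values were thus not confined to contigs. In the single-replicate lists, 85.3% of 320 contig peaks of replicate 1 and 84.2% of 291 of replicate 2 were shared.

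For these contig peaks, the median −log10 p was 1.46 times that of chromosome peaks with the same signal value (95% bootstrap interval 1.33 to 1.59). That lay between the bound of at least 2 set for a high local read depth, as from repeat copies collapsed in the assembly, and the bound of 1.2 set against it, so this explanation stays open. A stronger enrichment of the mark, if the signal value measures it, also stays open, since the median contig signal value (3.47) was at percentile 69.2 of the chromosome peaks, with a 95% bootstrap interval of 51.7 to 76.8 that includes the bound of 75 set against it. No biological explanation beyond this was tested.

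Chromosome 7 had 2.74 times the peak density of the genome. Weak peaks near the calling threshold are argued against, because the density was 3.07 times that of the genome among peaks at or above the median signal value and 2.42 times among those below it, a gap with a 95% bootstrap interval over 1 Mb windows of 0.256 to 1.05 (0.424 ± 0.0488 in the replicates' own lists, SD, n = 2). GC content alone is also argued against, since chromosome 11 has a GC content of 43.8%, above the 43.1% of chromosome 7, and a relative density of 0.861. Zinc finger and vomeronasal gene clusters as the whole cause stay open. Without peaks and sequence within 100 kb of the listed genes, the relative density was 2.18, still above the 1.51 of chromosome 17, the densest other autosome. In the replicates' own lists the gap to the densest other autosome was 0.357 ± 0.0290 (SD, n = 2). Both replicates share the same genome, so this spread does not measure variation along it. Over 1 Mb windows, the 95% bootstrap interval of the gap in the replicated list, −0.140 to 1.53, includes 0. The zinc finger list took only Zfp symbols with a number, so zinc finger genes with other symbols were not removed as such. The clusters could account for part or all of the excess, and no biological explanation was tested beyond these.

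Replicate 1 held 2190 X peaks and replicate 2 held 1606, a share of all peaks 1.42 times as high. The shared X peaks numbered 310 and 303, counts that are close by construction because they come from the same overlaps. X was the least shared chromosome in both. X peaks weaker in signal value are argued against: 14.2% were shared in replicate 1 (Wilson 95% interval 12.8 to 15.7) and 18.9% in replicate 2 (17.0 to 20.9), against 29.8% and 27.6% for autosomal peaks of the same signal value. X peaks weaker in −log10 p stay open, since that match did not cover it. The X share of the peaks fell from 4.48% to 2.77% in replicate 1 at a −log10 p of at least 5. In replicate 2 it fell from 3.16% to 2.47%. No lower calling threshold was seen in replicate 1, whose lowest −log10 p was 2.058, against 2.032 in replicate 2 (lowest signal values 1.34 and 1.28). These minima lie near the same floor and do not measure how many weak peaks each list holds. At a −log10 p of at least 5 the ratio of X shares was only 1.12 (95% interval 0.983 to 1.27), so an excess of weak X peaks in replicate 1 stays open. A higher female share in the replicate 1 pool, a hypothesis that came from the counts themselves (17 Y peaks in replicate 1 and 30 in replicate 2), stays open: at a −log10 p of at least 5 the odds ratio of X against Y peaks was 1.40 (95% interval 0.568 to 3.80, Fisher's exact p = 0.536). The −log10 p of X peaks relative to autosomal peaks of the same signal value, tried first, had a median ratio of 1 in both replicates. Signal values were often tied, and in replicate 1 at least 4887 peaks had a value of 3.08. Whether the ties gave that ratio was not tested, and it was not used to judge the female share.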

How the results depend on the processing

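Of 219 values recomputed under alternatives, 182 kept their direction and side of the threshold, or stayed within their error or 1.5 times for counts of peaks. The number of gene lists past the threshold was 4 in the report and between 3 and 6 over 9 alternatives. Imprinted genes and clustered protocadherins passed in all 9, while olfactory receptors and cytochromes P450 passed only against length-matched lists. Of the 54 genes named, 45 still had a peak at a −log10 p of at least 5 and 48 among the stronger peaks. The settings with replicated peaks that overlap a peak of each replicate, and with the histone and X-linked lists as first written, were added after the data were seen. Where values changed, the cause was not tested.

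The Spearman rho was 0.289 for reciprocal overlaps of at least 50% and 0.262 for −log10 p. Of the peaks called on both replicates, 96.0% were replicated at a −log10 p of at least 5. The promoter share passed the test at that threshold (3.55%), and within 2 kb it was 4.96%, against 5.14% after rotation, with no call (adjusted permutation p = 0.651). Between each replicate alone it ranged from 2.26% to 2.68%, and the exon share from 3.34% to 3.57%. For peaks near transcript starts, zinc finger genes (6.91%) and vomeronasal genes (6.42%, against 3.57% after rotation) no longer passed, at 2.17 and 1.80 times rotation, and vomeronasal genes lost the call with peaks in each replicate (16.8%). Over each replicate alone, the marked share ranged from 30.3% to 32.1% for vomeronasal, 34.8% to 58.7% for germline, 7.69% to 9.23% for X-linked, 9.38% to 14.1% for defensin, 2.11% to 4.21% for histone and 7.69% to 10.3% for Hox genes. Over all protein-coding genes, the share below rotation turned to 5.89% at a −log10 p of at least 5, above rotation with no call, and was no longer past the threshold among the stronger peaks (8.94%) or near transcript starts (2.13%). Directions also reversed, with no call, for histone genes among the stronger peaks (1.05%), for X-linked genes against length-matched lists (4.62%), and for defensins near transcript starts and with peaks in each replicate (1.56% in both). Relative to the genome, the density of chromosome 7 was 3.13 at a −log10 p of at least 5, 3.07 among the stronger peaks, 2.93 with peaks in each replicate and between 2.09 and 2.19 in each replicate alone, where that of X was 0.511 to 0.726. Depth is unknown, so it was not possible to say which of these shifts come from fewer reads.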

Other observations

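The gene types, symbol families and windows below were all chosen after the data were seen.

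Some of the densest regions held gene families outside the lists. The 100 densest windows of 1 Mb, of 2737, held 32.0% of the replicated peaks on the main chromosomes, and 8 of the 15 densest lay on chromosome 7. The protocadherin window at chromosome 18, 37000001 to 38000000, led with 215 peaks. It was followed by a window of secretoglobin genes, such as Scgb2b24 and Scgb1b24, at chromosome 7, 33000001 to 34000000, with 194. Genes of the Psg and Ceacam families, which encode immunoglobulin-like glycoproteins of placenta and epithelium, lay in the next window, at chromosome 7, 17000001 to 18000000, with 187. On chromosome 12, the window at 114000001 to 115000000 had 148 peaks and no protein-coding gene. Genes of other types were not listed for the windows, so it is not shown to be free of genes. On chromosome 13, the window at 61000001 to 62000000, with the cathepsin genes Ctsj, Ctsq, Ctsr and Cts6, had 107.

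Immunoglobulin variable segments, which encode parts of antibodies, were marked more often than rotation gave: 17 of 218 genes (7.80%, against 0.488%) and 17 of 158 pseudogenes (10.8%, against 0.455%). Of 144 T-cell receptor variable segments 1 was marked (adjusted permutation p = 1). Processed pseudogenes (181 of 9940, 1.82% against 0.815%) and unprocessed pseudogenes (127 of 2642, 4.81% against 2.36%) also exceeded rotation, as did long intergenic RNA genes (567 of 5854, 9.69% against 8.42%) and the type named miscellaneous RNA (12 of 562, 2.14% against 0.461%). The adjusted permutation p was 0.00542 for each of these types except the T-cell receptor segments (two-sided, Benjamini-Hochberg over 19 gene types).

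Families of at least 10 protein-coding genes with a shared symbol root outside the lists numbered 253. The rotation test called 0 of them after adjustment (smallest adjusted permutation p = 0.505). The smallest p that the rotations can give, 0.002, cannot pass after adjustment over 253 families unless many of them reach it together. The lack of calls therefore does not argue against a mark in any family. Unadjusted, 6 families had a p below 0.05. Of these 6, 3 lay below rotation: the Wdr family with 5 of 64 genes marked (7.81%, against 19.6%, unadjusted permutation p = 0.004), Cdc with 0 of 33 (against 16.9%, unadjusted permutation p = 0.004) and Mettl with 0 of 28 (against 13%, unadjusted permutation p = 0.034). The other 3 lay above it: the secretoglobin family with 9 of 34 (26.5%, against 3.38%, unadjusted permutation p = 0.00599), Ceacam with 7 of 15 (46.7%, against 13.2%, unadjusted permutation p = 0.046) and Klra with 5 of 11 (45.5%, against 9.94%, unadjusted permutation p = 0.04995).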
